A study of Mus musculus with 8 samples.

How the data were processed

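Erythroid progenitors were purified from C57BL/6 mouse fetal livers by magnetic sorting and cultured for 24 h with erythropoietin, per the labels. Ribosomal RNA was removed from total RNA, strand-specific libraries were made with dUTP marking and sequenced on a HiSeq2000, per the labels. Reads were aligned with TopHat2 2.0.11 to mm9 and counted per gene with HTSeq, per the submitters' processing notes. The version of HTSeq, the annotation release and the strand setting are not given. The authors deposited raw counts for 1 file per library, with 37620 Ensembl gene IDs and 5 summary entries, and the files were used as counts without any normalisation by the authors. The summary entries gave the counts outside genes, which were expressed as a share of uniquely placed counts (in genes, ambiguous or outside genes).

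GENCODE M21 on GRCm38 supplied symbols for 87.4% of the IDs, as well as biotypes, exon lengths and gene positions. Positions printed are on GRCm38 and were not used to count reads. Some IDs of the older annotation had no match, and 23 entries of the fixed gene lists could not be matched.

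The libraries fell into 6 groups by their labels. A single edgeR 4.0.16 fit (R 4.3.3) held all 8 libraries, with TMM scaling, filterByExpr on the groups (15355 genes tested), and quasi-likelihood F-tests without robust estimation. Adjusted p-values are Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The only repeated samples were the 2 hairpins of each target, which gave 2 residual degrees of freedom, and each single control library was assumed to vary like them. The prior degrees of freedom came to 397, so that each gene's spread was drawn almost wholly to the trend over all genes, and a gene whose hairpins lie far apart could still pass. The common dispersion was 0.145. The SE of a log2 fold change is its size divided by the square root of F. Levels are TMM CPM, and log2 differences between single libraries used a prior count of 2.

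The difference of the knockdown effects was tested as a contrast in the same fit. Shared calls were compared with Fisher's exact test and with the number expected from independent draws. For the overexpression pair, with 1 library per arm, log2 differences carry a 95% exact conditional binomial interval of the count ratio, and list medians were placed among 10000 random lists of the same size matched on mean expression in 20 bins. The 33 gene lists covered erythroid pathways, proliferation, stress, RNA processing and markers of other cell types. They were tested with camera at a preset correlation of 0.01, repeated with an estimated correlation, and with fry (limma 3.58.1), adjusted over the 33 lists. The agreement of 2 hairpins was set beside 100 simulations without an effect that shared the control library.

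Groups, tests, gene lists, the naming rule and 21 of the alternative settings were chosen before the data were examined. The genes named were the targets and, for each knockdown, the 12 highest and 12 lowest log2 fold changes among genes that passed with both hairpins on the same side of the control and a mean of at least 5 CPM. Where fewer passed, up to 6 places in a direction went to the smallest unadjusted p, and those genes are said not to pass. From each list, up to 4 passing members with the largest change were named, or up to 2 members of at least 5 CPM where none passed. In the overexpression pair, the 12 highest and 12 lowest genes of at least 5 CPM outside the range of all 3 controls were eligible. Predicted gene models, small RNAs and pseudogenes were counted only. After values were seen, the rule on the side of the control was made stricter by rounding differences to 6 decimals, since a gene with 0 counts in a hairpin library and its control had passed it through numerical noise.

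Alternatives were DESeq2 1.42.0, limma-voom, DESeq2's size factors within edgeR, upper quartile scaling, no filter, a filter of 5 CPM in 2 libraries, removal of the 20 most abundant genes, robust estimation, a test against 1.5-fold, other control libraries, other prior counts, fits of 3 libraries and each hairpin library left out in turn. A further 4 settings were added after the data were seen: protein-coding genes only, the hnRNPU hairpin libraries left out, the 2 unmatched IDs and mitochondrial ribosomal RNA left out, and every library thinned to the 2612916 gene counts of the shallowest. Thinning drew each count from a binomial distribution with a fixed seed. A first version with edgeR's own thinning routine distorted proportions between genes and was replaced after its result was seen.

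The fit was tested on simulated data with the depths and dispersions of these libraries. In the Bloodlinc comparison it recovered 80% of genes changed 16-fold, 44% at 8-fold, 18% at 4-fold and 2% at 2-fold with 0 false calls. In the hnRNPU comparison it recovered 66%, 46%, 14% and 0% with 3 false calls. The simulated control libraries varied like the hairpins by construction. These false calls therefore say nothing of calls that a control library standing apart would give. A simulated list of 25 genes shifted 2-fold was called by camera in both comparisons and 0 of 30 unshifted lists were. The simulated genes were drawn independently, so this cannot tell how often the preset correlation gives false calls where genes of a list vary together. In a simulated overexpression pair, a list shifted 1.25-fold lay at percentile 100 of random lists. That pair had independent genes and a fixed dispersion far below the fitted common dispersion of 0.145, so it is no measure of the background in the real pair.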

Results

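Total RNA depleted of ribosomal RNA was sequenced from mouse erythroid progenitors, the precursors of red blood cells. The cells came from fetal livers of E14.5 embryos, received short hairpin RNAs or expression vectors by transduction, and differentiated with erythropoietin for 24 h. The 8 libraries formed 6 groups. A knockdown of Bloodlinc, a long noncoding RNA, had 1 control hairpin library and 1 library for each of 2 hairpins. A knockdown of Hnrnpu, which encodes the nuclear RNA-binding protein hnRNP U, had the same layout with its own control hairpin library. Overexpression of Bloodlinc was compared with an empty vector, with 1 library each.

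Counts in genes came to 23771372 in the Bloodlinc control hairpin library, and to 23682993 and 26737017 with Bloodlinc hairpins 1 and 2. The empty vector library held 31706823 and the Bloodlinc vector library 34540691. The hnRNPU control hairpin library held 33820556, but hnRNPU hairpins 1 and 2 held 2931627 and 2612916. In those 2 libraries, 89.7% and 86.6% of the uniquely placed counts lay outside genes, against 21.7% to 30.1% in the other 6 libraries. Of the counts in genes there, 32.6% and 22.6% fell on 2 gene IDs that the reference annotation does not hold, against at most 0.122% elsewhere. Mitochondrial ribosomal RNA took 18.1% to 28.9% of the counts in genes over the 8 libraries. A count of 0, taken as a floor of 3 counts, allows up to 0.0869 CPM (counts scaled to the total of the library) in the deepest library and 1.15 CPM in the shallowest. Intervals and floors cover counting error only, and p-values measure only the spread between these samples, since the labels do not say whether the 2 hairpins of a target came from separate cultures or animals.

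**Figure D1:**
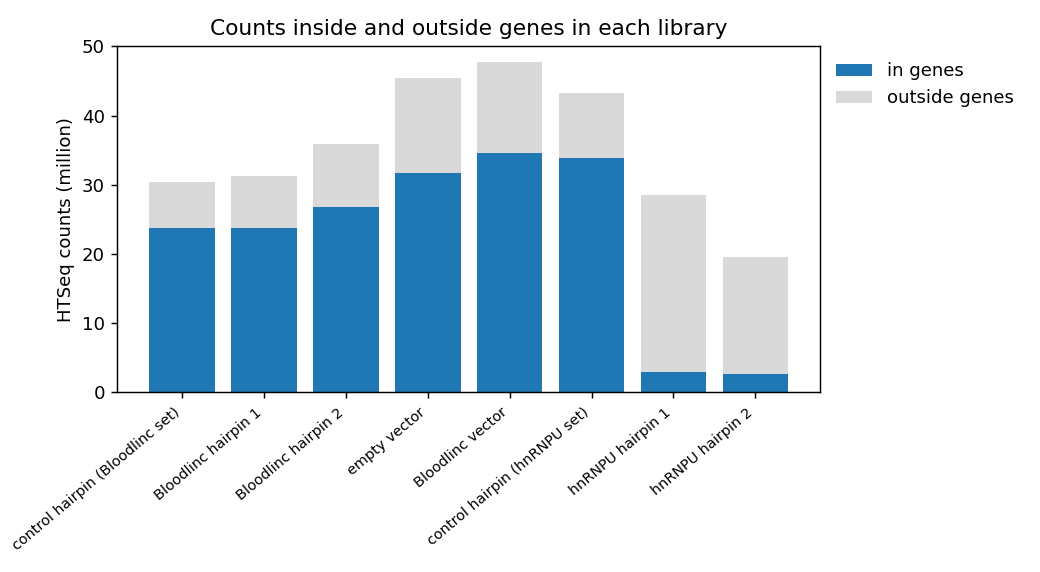
Counts from HTSeq in each of the 8 libraries, split into counts in genes and counts outside genes. The hnRNPU hairpin libraries held 2931627 and 2612916 counts in genes, and the other 6 libraries 23682993 to 34540691.

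Bloodlinc (ENSMUSG00000087330) lies on chromosome 11 from 102375549 to 102377020 on the minus strand of GRCm38, 9345 bp from Slc4a1 (ENSMUSG00000006574), the gene of the red cell anion exchanger band 3. Bloodlinc RNA stood at 4.46 CPM (87 counts) with its control hairpin and at 1.97 ± 0.312 CPM (SD, n = 2) with the Bloodlinc hairpins, which held 50 and 54 counts. The log2 fold change of −1.18 (SE 0.81) did not pass edgeR's test (adjusted p = 1). Slc4a1 was at 13367 CPM with the control hairpin and at 6608 ± 1557 CPM (SD, n = 2) with the Bloodlinc hairpins, a log2 fold change of −1.02 (SE 0.69; adjusted p = 1) that turned to 0.0774 against the other control hairpin library. Hnrnpu (ENSMUSG00000039630) was at 588 CPM with its control hairpin and at 349 ± 33.6 CPM (SD, n = 2) with the hnRNPU hairpins. Its log2 fold change of −0.75 (SE 0.58) did not pass either (adjusted p = 0.73) and turned to 0.27 against the other control hairpin library. In the hnRNPU knockdown, Bloodlinc stood at 4.35 CPM in the control and at 2.17 ± 1.39 CPM (SD, n = 2) on 2 and 8 counts, with a log2 fold change of −0.94 (SE 0.91; adjusted p = 0.801). Slc4a1 had a log2 fold change of −0.06 (SE 0.71; adjusted p = 0.991) there, a sign that turned with DESeq2's size factors (0.10), with upper quartile scaling (0.13) and without hnRNPU hairpin 2 (0.15). Bloodlinc had 52 counts with the empty vector and 250 with the Bloodlinc vector, a log2 difference of 2.05 with a 95% counting interval of 1.68 to 2.58. These are 1.26 and 5.46 CPM, so the Bloodlinc vector library lay little above the 2 control hairpin libraries (4.46 and 4.35 CPM). The empty vector library lay below both.

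**Figure D2:**
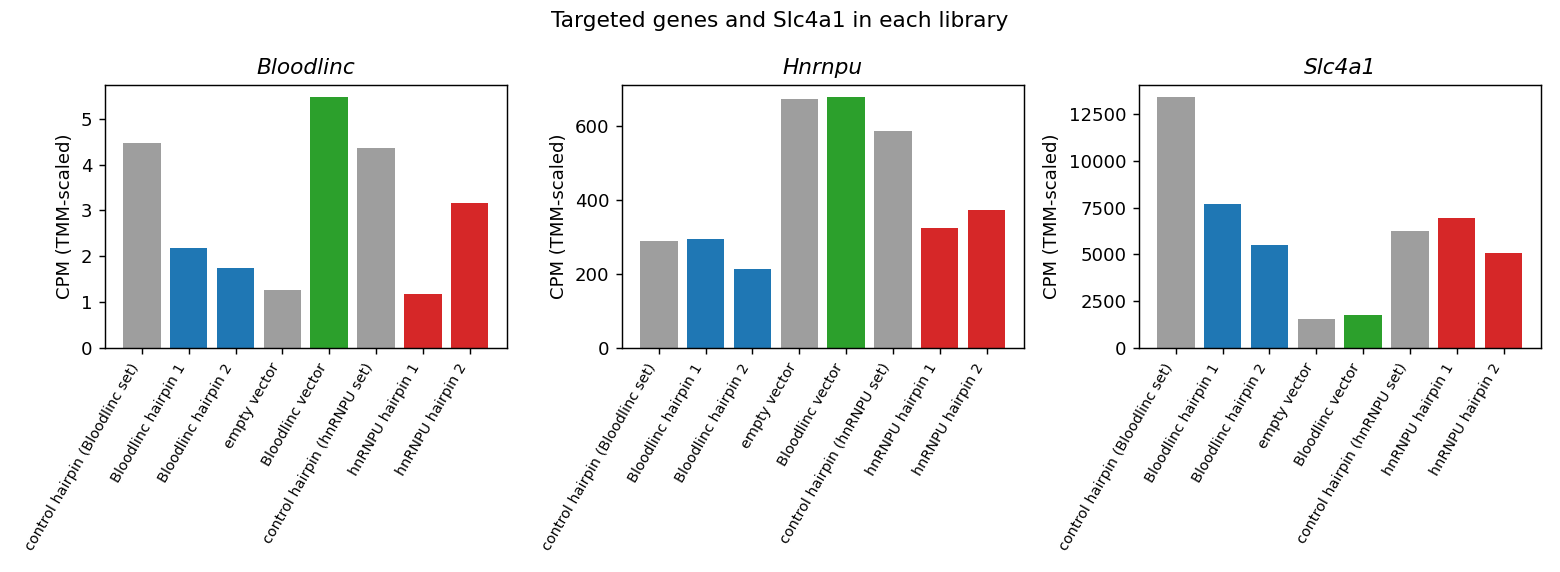
Normalised level of Bloodlinc, Hnrnpu and Slc4a1 in each of the 8 libraries, in TMM CPM, 1 bar per library. Bloodlinc ranged from 1.18 to 5.46 CPM, Hnrnpu from 214 to 678 CPM and Slc4a1 from 1555 to 13367 CPM.

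The Bloodlinc knockdown asked which genes change in differentiating erythroid cells when this RNA is targeted. Of 15355 genes tested, 15 rose and 4 fell, all of them protein-coding. Those that rose included Col18a1, which encodes a basement membrane collagen, from 6.25 CPM to 55.2 ± 7.42 CPM (SD, n = 2; log2 fold change 3.14, SE 0.67, adjusted p = 0.00991). Mgarp, a mitochondrial protein gene, rose from 6.77 to 57.1 ± 7.01 CPM (SD, n = 2; log2 fold change 3.08, SE 0.70, adjusted p = 0.0213). Cd82, a membrane tetraspanin gene, fell from 93.1 to 16.3 ± 0.339 CPM (SD, n = 2; log2 fold change −2.52, SE 0.52, adjusted p = 0.00991).

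The largest fold changes belonged to genes near 0 in the control. Dglucy, whose product acts on D-glutamate, went from 0.256 to 5.13 and 11.3 CPM with hairpins 1 and 2 (log2 fold change 4.98). Muc6, a mucin gene, and Rgs11, a regulator of G protein signalling, rose by log2 fold changes of 4.95 and 4.92. For several genes the rise lay mainly in the hairpin 2 library. Cgn, the tight junction gene cingulin, stood at 1.23 and 28.8 CPM with hairpins 1 and 2 against 0.666 CPM in the control. The water channel gene Aqp8 stood at 4.08 and 64.1 CPM against 2.36 CPM, and Spns2, a sphingosine-1-phosphate transporter gene, at 17.5 and 183 CPM against 15.4 CPM. The ion channel gene Trpv2 stood at 10.9 and 90.1 CPM against 5.48 CPM, Nabp1 at 14.7 and 67.6 CPM against 5.18 CPM, and Pgm1 at 20.2 and 60.2 CPM against 5.07 CPM. Plekha2 (log2 fold change 3.37) stood 1.81 and 4.06 log2 units above the control with hairpins 1 and 2. Fos, an immediate early transcription factor gene, fell by 2.58 on the log2 scale (log2 fold change 0.16 against the other control hairpin library), Nyx fell by 2.53, and Vgf, which encodes a secreted neuropeptide precursor, fell by 2.28. Apol11b (log2 fold change −2.34, adjusted p = 0.141) and the histone gene Hist1h2bk (−1.77, adjusted p = 0.248) did not pass. Of the 19 genes that passed, 16 had both hairpins on the same side of the control (Mical1, Trim16 and Stard9, named for this after their values were seen, did not), and 613 genes lay at an unadjusted p under 0.05.

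The 19 calls were lost in several settings. Without Bloodlinc hairpin 2, without either hnRNPU hairpin, or in a fit of the 3 libraries alone, edgeR called 0 genes, with 291, 501 (without hnRNPU hairpin 1), 497 (without hnRNPU hairpin 2) and 369 genes at an unadjusted p under 0.05. Each of these fits also has fewer residual degrees of freedom, and with hairpin 1 alone the log2 difference from the control was still 2.98 for Col18a1, 2.93 for Mgarp, 3.96 for Dglucy, −2.49 for Cd82 and −3.28 for Nyx. Without Bloodlinc hairpin 1, 63 genes passed, 17 of them among the 19, and against the other control hairpin library 258 rose and 785 fell, with 13 of the 19 among them. DESeq2 called 5 genes, all among the 19 (Dglucy, Rgs11, Col18a1, Mgarp and Cd82), and limma-voom called 0 with 636 at an unadjusted p under 0.05.

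As groups, most erythroid lists lay lower with the Bloodlinc hairpins by camera with a preset correlation, although no member passed alone. None of these lists held with an estimated correlation (adjusted p from 0.448 to 0.540). All 15 heme synthesis genes were lower (median log2 fold change −0.62), among them Alas2, the first enzyme of the pathway in red cells (−0.84, SE 0.69). Alas2 turned to 0.37 against the 3 pooled controls and to 1.35 against the other control hairpin library. Of 24 genes of the red cell membrane and skeleton, 22 were lower (median −0.49), and Mpp1 stood at −1.02. Of 27 genes of late maturation, mitophagy and enucleation, 24 were lower (median −0.70), with Xpo7 at −1.45 and Bpgm, the gene of bisphosphoglycerate mutase, at −1.15. The 7 globin genes had a median of −0.83, with Hbb-bt at −1.63 and Hba-a2 at −1.26, and 2 of the 7 were higher. The 20 erythroid transcription factors had a median of −0.41, with Lmo2 at −0.90 and Tal1 going from 665 CPM to 448 and 216 CPM. Iron uptake and handling genes (median −0.21, 8 of 20 higher; Steap3 1.19, or −0.16 against the other control hairpin library) and EPO-STAT5 target genes (median −0.11, 7 of 20 higher; Erfe −1.13) were not called (adjusted p = 0.281 and 0.0824).

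Proliferation genes lay lower in the Bloodlinc knockdown by the same camera test, with 0 members that passed and 0 lists that held with an estimated correlation (adjusted p = 0.609 for DNA replication and 0.540 for mitosis). All 28 DNA replication genes were lower (median log2 fold change −0.47; Mcm6 −1.33), as were all 25 mitosis genes (median −0.60; Mki67 −1.12, Nusap1 −1.13, which was 0.0671 against the other control hairpin library). All 49 replication-dependent histone genes were lower (median −1.20; Hist1h4c −1.66), and 15 of them fell when adjusted over the list alone against 0 over all genes. Of 75 ribosomal protein genes 74 were lower (median −0.47; Rps4x −1.32, Rpl8 −1.10). The hnRNP genes (median −0.19) and splicing factors (median −0.26) were lower by less. Heat shock and immediate early genes had a median of −0.35, or −0.41 with members at 0 counts set to their bound, and Fos was the member that fell. Among markers of other blood cells, granulocyte genes had a median of −1.07 (S100a8 −1.36, Mpo −1.11; 3 fell when adjusted over the list alone) and mast cell genes −0.54. Macrophage genes went both ways, with Csf1r at 2.85 (adjusted p = 0.136) and Lyz2 at −0.85. The Csf1r value rested on hairpin 2 (1.93 and 22.5 CPM with hairpins 1 and 2 against 1.69 CPM), and was 0.19 without it and −0.0230 against the other control hairpin library. Higher as groups were 23 cholesterol synthesis genes (median 0.50, 21 higher; Mvd 1.45, Lss 1.20) and 19 glycolysis genes (median 0.46; Pkm 1.78, Gpi1 1.46). Both calls were lost with an estimated correlation (adjusted p = 0.492 and 0.448) and without Bloodlinc hairpin 1, where 0 lists were called higher.

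By camera with a preset correlation of 0.01, 14 of these lists were lower and 2 higher among 33 tested. None of the 16 held with an estimated correlation, where their adjusted p ran from 0.448 to 0.711, and fry called 0 of the 33. In the interferon response list, the median of 0.19 and mean of 0.17 were positive while camera placed it lower without a call (adjusted p = 0.505), with Oasl2 at −1.75 and Rsad2 at −1.38. The p53 target list also differed in sign between its median (0.22) and camera's direction (down, adjusted p = 0.847), with Gadd45a at −1.53 and Mdm2 at −1.09.

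**Figure D3:**
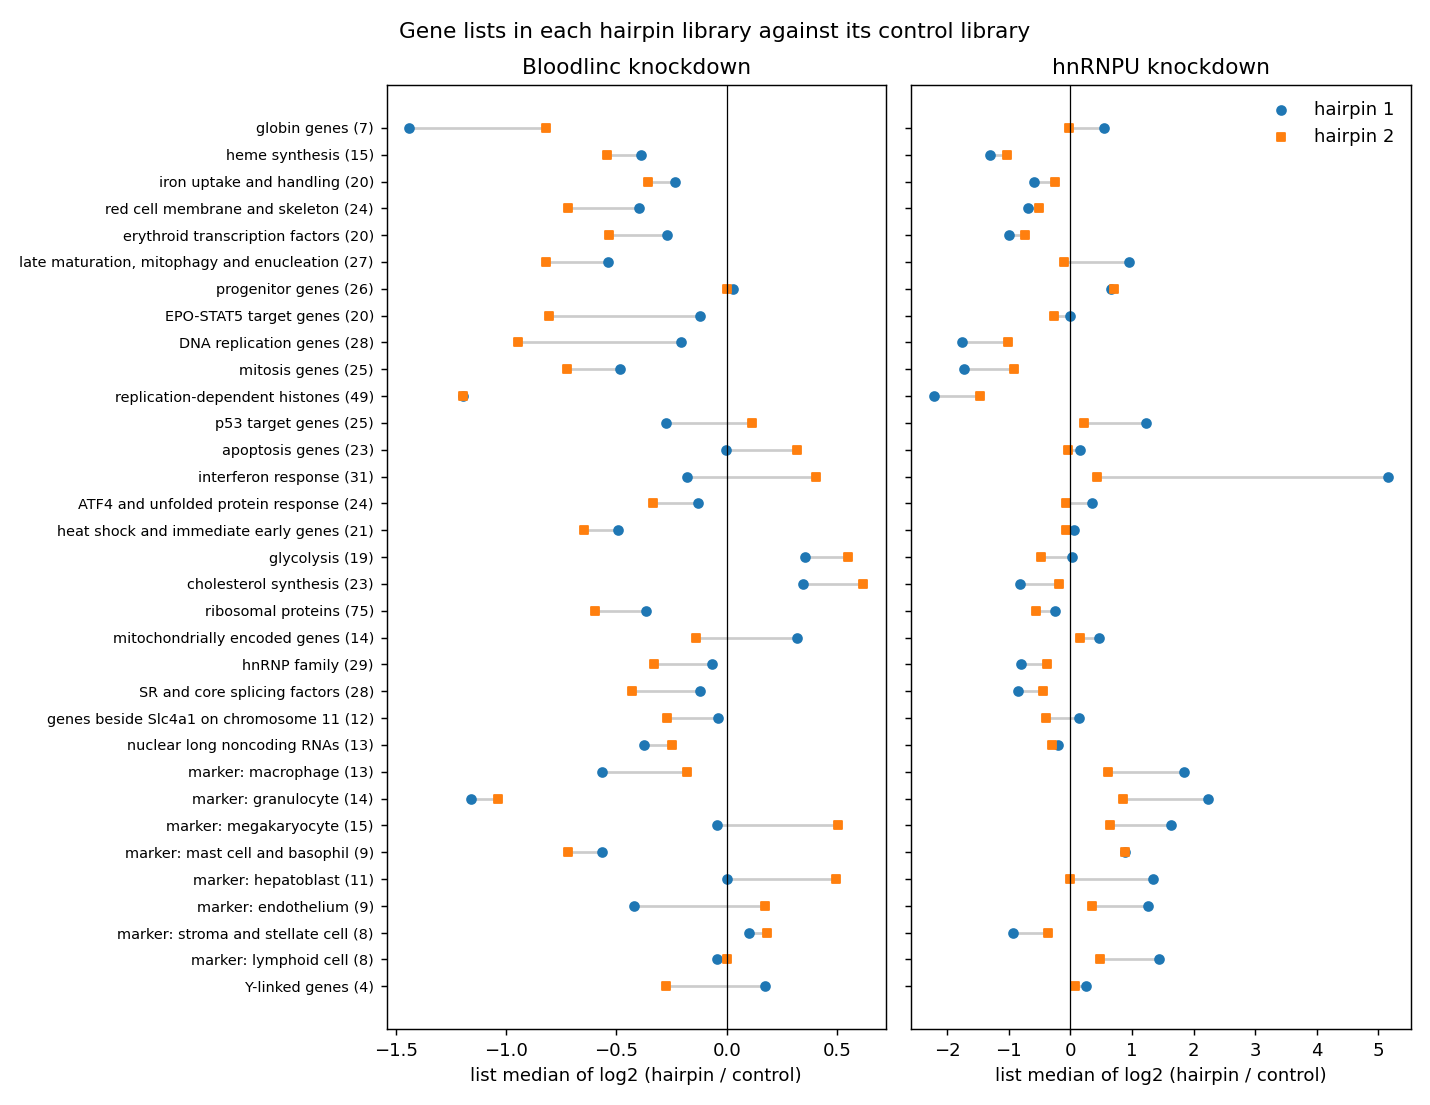
Median log2 difference from the control hairpin library for each fixed gene list, 1 point per hairpin, in the Bloodlinc and the hnRNPU knockdown. The interferon response list stood at 5.15 with hnRNPU hairpin 1 and at 0.44 with hnRNPU hairpin 2.

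Across genes, which are not independent replicates, the differences of the 2 Bloodlinc hairpins from their shared control correlated with r = 0.425. Libraries simulated with no effect and the same shared control gave a mean r of 0.517 over 100 simulations. The covariance was 0.302 against a simulated mean of 0.375. The 2 hnRNPU hairpins had r = 0.399 against a simulated mean of 0.294, with a covariance of 0.673 against 0.333. The simulations gave the control the spread seen between hairpins, while the spread of a single control library was not measured. They therefore cannot tell how much of either agreement comes from the shared control.

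The hnRNPU knockdown asked which genes depend on this nuclear RNA-binding protein during the same differentiation. Of 15355 genes, 89 rose and 46 fell. Interferon-induced genes made the largest group to rise, and 22 of the 31 tested passed, or 30 when adjusted over the list alone. Replication-dependent histone genes made the largest group to fall, with 14 of 49, or 40 when adjusted over the list alone. Ifit1, an antiviral RNA-binding protein gene, rose from 0.971 CPM to 492 and 11.8 CPM with hairpins 1 and 2 (log2 fold change 8.01, SE 0.88, adjusted p = 2.97e-14).

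The rise of the interferon genes lay almost wholly in the hairpin 1 library. The list median was 5.15 on the log2 scale with hairpin 1 and 0.44 with hairpin 2, and 4.83 in the fit of both, or 4.33 with members at 0 counts set to their bound. Irf7, the interferon regulatory factor gene, stood at 1.68 CPM in the control and at 122 and 4.33 CPM with hairpins 1 and 2. Usp18, which encodes an inhibitor of interferon signalling, was at 59.1 CPM with hairpin 1 and at 0.394 CPM (1 count) with hairpin 2, against 0.393 CPM (15 counts). Only 16 of the 31 members reached 1 CPM in the control. A count of 0 with hairpin 2 allows up to 1.15 CPM of the library total, or 1.18 TMM CPM. A small rise of the other members could be missed there. Oas2, an antiviral synthetase gene, had 1 count in the control, 69 with hairpin 1 and 0 with hairpin 2, a ratio of 622 with a counting interval of 108 to 24910. Rtp4 had 3, 29 and 0 counts, a ratio of 87.1 (27.0 to 447). Ifit3 had 0, 39 and 0 counts and was at least 90.8-fold higher by the counting interval, and at least 117-fold against a floor of 3 control counts if the counting error of the 39 counts is left aside. The Schlafen genes Slfn5, Slfn4 and Slfn8 (log2 fold changes 6.69, 5.48 and 5.31) and Ddx60, Igtp, Ifi204 and Xaf1 (6.28, 5.57, 5.32 and 5.07) rose with the same split between hairpins. By camera the list was higher with a preset correlation, and its adjusted p was 0.508 with an estimated correlation. Without hairpin 1, 0 interferon genes were among the 7 genes that edgeR called, with 297 genes at an unadjusted p under 0.05, and without hairpin 2, 17 were among 59. Outside the naming rule and chosen after their values were seen, those 7 were 5 gene IDs absent from the annotation, Lars2 and Map7d2.

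Counts of Lars2, a mitochondrial leucyl-tRNA synthetase gene, were higher in both hairpin libraries, at 1648 and 598 CPM against 8.29 CPM (log2 fold change 7.08). Leftover ribosomal RNA stays open as an explanation for the make-up of these 2 libraries. Whether it adds to the counts of Lars2 was not settled, so they may not measure its mRNA. Map7d2, a microtubule-associated protein gene, stood at 0.210 CPM in the control and at 109 and 45.3 CPM (log2 fold change 8.49).

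Genes of chromatin and the cell cycle were lower with both hnRNPU hairpins. Camera called the histone, DNA replication and mitosis lists lower with a preset correlation. None of these 3 lists held with an estimated correlation (adjusted p = 0.508 for each). The histone list had a median log2 fold change of −1.75, or −1.73 with members at 0 counts set to their bound, with 47 of 49 lower. Among its members, Hist1h2ad fell from 127 CPM to 16.0 and 17.7 CPM (log2 fold change −2.92, SE 0.54, adjusted p = 9.23e-05). Hist3h2ba, Hist1h4j, Hist1h2ae, Hist1h3a and Hist1h2ag fell with log2 fold changes of −2.98, −2.69, −2.58, −2.45 and −2.28. Histone and interferon gene families hold near-identical copies, and reads placed at several loci were not in the gene counts. All 28 DNA replication genes were lower (median −1.38; Mcm5 −1.63, Ccne1 −1.62), none passed over all genes, and 27 fell when adjusted over the list alone. All 25 mitosis genes were lower (median −1.26; Cdc20 −1.81, Ccna2 −1.68), 0 over all genes and 14 when adjusted over the list alone. Most histone calls were lost when either hnRNPU hairpin was left out, in fits with fewer residual degrees of freedom. The histone list median was −2.21 with hairpin 1 and −1.46 with hairpin 2. Across genes, differences from the control went up with exon length (Spearman rho 0.143 and 0.180 with hairpins 1 and 2). Histone genes were short (median 572 bp of exons), while DNA replication and mitosis genes had medians of 4177 and 4354 bp. No length-matched lists were drawn for this knockdown, so a gene length bias was not tested.

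Among red cell genes, Aqp1 and Icam4, which encode a water channel and an adhesion protein of the red cell surface, fell with log2 fold changes of −2.02 and −1.95 (adjusted p = 0.0389 and 0.0462). Aqp3, another channel gene, fell by 2.79, and Pklr, the pyruvate kinase of red cells, fell from 344 to 55.7 ± 35.4 CPM (SD, n = 2; log2 fold change −2.62). The glucose transporter gene Slc2a4, the metallothionein gene Mt2, Arrdc2 and Med18 fell with log2 fold changes of −2.53, −2.32, −3.01 and −2.39. Of 15 heme synthesis genes 13 were lower (median −1.09; Cpox −2.05, adjusted p = 0.095; Alad −1.63, adjusted p = 0.208), with 6 that fell when adjusted over the list alone. The transcription factors Klf1 (−1.57, adjusted p = 0.222) and E2f4 (−1.47), the erythropoietin receptor gene Epor (−1.76, adjusted p = 0.0913) and its feedback gene Socs3 (−1.83, adjusted p = 0.0809) did not pass. The erythroid transcription factor list had a median of −0.76 and the membrane list −0.64. Late maturation genes had a median of 0.95 with hairpin 1 and of −0.11 with hairpin 2, with no call. Of 7 globin genes 1 rose, the embryonic gene Hbb-y (log2 fold change 2.76, adjusted p = 0.0355), at 33.5 CPM with hairpin 2 and 1.77 CPM with hairpin 1 against 2.68 CPM. Without hairpin 2 its log2 fold change was −0.60.

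Markers of several other cell types were higher with the hnRNPU hairpins. The list of 8 stroma and stellate cell genes had a median log2 fold change of −0.60 without a call. With members at 0 counts set to their bound or left out, its median was −0.07. None of the higher marker lists held with an estimated correlation (adjusted p = 0.508 for each). All 14 granulocyte genes were higher (median log2 fold change 1.73; 2.23 with hairpin 1 and 0.86 with hairpin 2). The neutrophil granule genes Ngp, Ltf and Lcn2 rose by 2.73, 2.71 and 2.31, and 9 rose when adjusted over the list alone. The macrophage perforin gene Mpeg1 rose (2.33, adjusted p = 0.0389) in a list with a median of 1.61, or 1.96 with bounds. Esam, an endothelial adhesion gene, rose from 2.68 to 24.8 ± 5.02 CPM (SD, n = 2; 3.21). Megakaryocyte genes (median 1.32; Itgb3 1.36), progenitor genes (median 0.80; Erg 1.47, Fli1 1.34) and mast cell genes (median 0.52; Hdc 0.89) were higher with no member that passed. Hmox1, the heme-degrading enzyme gene, and Zfp36, an immediate early gene, rose by 2.45 and 2.29. The p53 target list had a median of 0.81 (Trp53inp1 1.66). The hnRNP list (median −0.59; Ptbp1 −1.20), splicing factors (median −0.60; Snrpb −1.37), ribosomal proteins (median −0.41) and cholesterol synthesis genes (median −0.37) were lower. The nuclear RNAs Malat1 and Neat1 stood at 1.41 and 1.57 and did not pass.

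By camera with a preset correlation, 10 lists were higher and 10 lower. None held with an estimated correlation, where the adjusted p of these 20 ran from 0.508 to 0.618, and fry called 0. Of the 135 calls, 15 were IDs absent from the annotation, 129 had both hairpins on the same side of the control, and 1518 genes lay at an unadjusted p under 0.05. DESeq2 called 100 genes, 13 of them in the interferon list and 9 in the histone list. With limma-voom 9 passed, 0 of them in the interferon list and 0 in the histone list, with 1688 at an unadjusted p under 0.05. With TMM the median of all genes was −0.09 in this comparison. It was 0.03 with DESeq2's size factors, where 126 genes rose and 38 fell, and 0.07 with upper quartile scaling, where 130 rose and 33 fell. With robust estimation 30 rose and 35 fell, with 4 of these 65 in the interferon list and 12 in the histone list.

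Comparing the knockdowns asked whether Bloodlinc and hnRNP U affect the same genes. The overlap of calls could not answer this. None of the genes that rose or fell was shared in direction, but only 0.0869 and 0.0120 were expected by chance (Fisher's exact test, two-sided, p = 1 for each direction), and 2% and 0% of simulated 2-fold changes were recovered in the Bloodlinc and hnRNPU knockdowns. Nyx fell in the Bloodlinc knockdown and rose in the hnRNPU knockdown, with 0.0681 opposite genes from chance. The effects themselves differed for 50 genes by edgeR, 47 with the higher effect in the hnRNPU knockdown, among them Ifit1 (difference 8.66 on the log2 scale, SE 0.99) and Lars2 (8.26, SE 0.99). Aqp3 (−4.43, SE 0.85) and Mgarp (−5.73, SE 1.29) differed the other way. Without hnRNPU hairpin 1, 6 genes differed, and without hairpin 2, 30. Across genes the fold changes of the knockdowns correlated with r = 0.134 and rho = 0.176, and with r = 0.220 under the filter of 5 CPM. Without Bloodlinc hairpin 1 or 2, r was 0.174 and 0.0312. Without hnRNPU hairpin 1 or 2, r was 0.151 and 0.0861.

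The overexpression pair asked what follows when more Bloodlinc is present than with the empty vector. With 1 library per arm there was no test, and values carry counting intervals only. Megakaryocyte and platelet genes were the most raised list, with 14 of 15 higher and a median log2 difference of 0.53. The platelet chemokine genes Pf4 and Ppbp were higher by 0.67 (0.53 to 0.82) and 0.63 (0.36 to 0.92), and Thbs1, the thrombospondin gene, by 0.53 (0.46 to 0.60). All 13 macrophage genes were lower, with a median of −0.59, and the mannose receptor gene Mrc1 stood at −0.59 (−0.84 to −0.36). The megakaryocyte list did not go the opposite way in the Bloodlinc knockdown. There its median log2 fold change was 0.31, with 10 of 15 higher and no call. Its medians were −0.04 with Bloodlinc hairpin 1 and 0.51 with hairpin 2.

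Erythroid lists were slightly higher with the Bloodlinc vector. Genes of the membrane and skeleton (median 0.15; Tmod1 0.25), late maturation (0.14, 26 of 27 higher), erythroid transcription factors (0.11; Klf3 0.36), replication-dependent histones (0.11) and heme synthesis (0.09; Alas2 0.15) lay above the range of 95% of 10000 random lists matched in size and expression. Globin genes (median 0.09) and iron uptake and handling genes (0.03) lay inside that range. Slc4a1 was higher by 0.16 (0.15 to 0.18) and the adult globin gene Hbb-bt by 0.21 (0.21 to 0.22). All 14 mitochondrially encoded genes were lower (median −0.17; mt-Nd2 −0.29). Progenitor genes (median −0.07), with Myb at −0.35 (−0.42 to −0.29), and granulocyte genes (median −0.13) also lay below that range. In all, 18 of 33 lists lay outside the range of 95% of random lists, and in 1 simulated pair 9% of 200 unshifted lists did so. That simulation had independent genes and a dispersion far below the fitted common dispersion, so the 9% is no measure of the background here. The 12 highest named genes included Mrvi1 (0.66), Nab2 (0.58), Mnt (0.57) and Polr2a (0.51), and the lowest Eda2r (−0.60), Tmtc1 (−0.51), Abcg1 (−0.49), Rundc3a (−0.38), Tifa (−0.34), Vsir (−0.32), Cd55 (−0.30) and the cell cycle inhibitor gene Cdkn1a (−0.28).

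**Figure D4:**
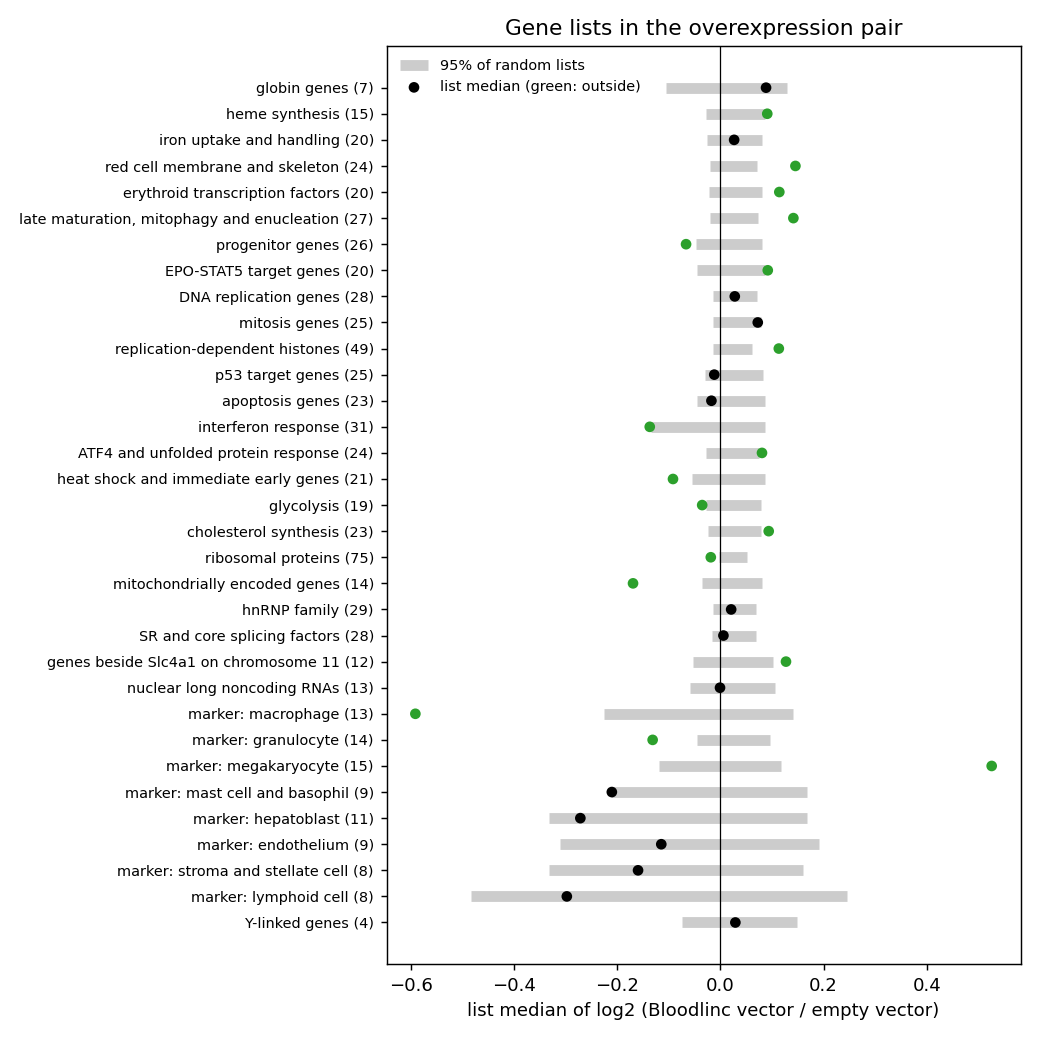
Median log2 difference between the Bloodlinc vector and empty vector libraries for each fixed gene list, with the range of 95% of 10000 matched random lists. The megakaryocyte list stood at 0.53 and the macrophage list at −0.59.

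Differences in this pair were small beside those between control libraries. Of 15355 genes, 269 were at least 2-fold apart, 57 higher and 212 lower with the Bloodlinc vector, and at a mean of 5 CPM or more 0 were higher and 3 lower. These 3 were IDs absent from the annotation. The 3 pairs of control libraries had 1418 to 3394 genes at least 2-fold apart at that level. The SD of log2 differences was 0.131 in the overexpression pair and 0.823 to 1.46 between controls. Of the 19 genes called in the Bloodlinc knockdown, 12 (63.2%, exact Clopper-Pearson interval 38.4% to 83.7%) had the opposite sign in the overexpression pair, against 50.8% of other genes. These were 11 of the 15 that rose (73.3%) and 1 of the 4 that fell (25%), and 0 of the 19 were 2-fold apart in the opposite direction. Across genes the knockdown and the overexpression correlated with r = −0.02.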

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

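The tests on the shared decrease of Hnrnpu RNA, on macrophages or granulocytes, on the strand of counting and on slower maturation were chosen only after the result was seen.

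The effects of the knockdowns differed for 50 genes by the contrast of the effects in edgeR, which shares no library between its sides. Interferon-induced genes had the higher effect in the hnRNPU knockdown, with log2 differences of 8.66 for Ifit1, 7.19 for Xaf1, 6.16 for Slfn8, 5.55 for Igtp, 5.26 for Rsad2, 5.18 for Usp18, 5.02 for Irf7 and 4.28 for Oasl2. Neutrophil genes differed in the same direction, by 4.2 for Ngp, 3.51 for S100a8 and 3.24 for Lcn2. So did Lars2 (8.26), Nyx (5.17), Esam (4.30), Fos (3.92) and Vgf (3.26). Aqp3 (−4.43), Spns2 (−3.83) and Mgarp (−5.73) had the higher effect in the Bloodlinc knockdown. Counts outside genes made up 89.7% and 86.6% of uniquely placed counts in hnRNPU hairpins 1 and 2, a signal in entries that no comparison uses, against at most 30.1% in the control libraries.

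Interferon-induced genes were far higher with hnRNPU hairpin 1 and little higher with hairpin 2. Chance counts in a shallow library were argued against, since 31 of 31 members had a Poisson interval above that of the control with hairpin 1, against 10 with hairpin 2. A larger share of macrophages or granulocytes in their usual state was argued against by a list median 2.92 log2 units above the higher of both marker medians. However, Ngp and Ltf reached 1602 and 1297 CPM with hairpin 1 from 158 and 125 CPM. In the control, 6 of 13 macrophage and 14 of 14 granulocyte markers were at 1 CPM or more. How far the sorting for progenitors removed such cells was not measured. The decrease of Hnrnpu RNA shared by both hairpins (325 and 373 CPM against 588) stays open, since the ratio of list medians, hairpin 2 over hairpin 1, of 0.0850 restates the pattern and cannot test it. A response of the cells to hairpin 1 itself, or activated cells of another type, may also account for the pattern, and neither was tested.

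Most counts of the hnRNPU hairpin libraries lay outside genes, and 2 unmatched IDs held 32.6% and 22.6% of the rest. Counting on the wrong strand was argued against by the low strand of 977 opposite gene pairs, which held at most 0.00176 of the counts of the high strand in these libraries and 0.00103 to 0.00243 in the others. Genomic DNA was argued against by 985 olfactory receptor genes, which held at most 2.76 CPM of the counts outside genes, against 25.9 to 93.8 CPM in the others. For ribosomal RNA left after depletion, genes that rose shared 31-base words with annotated ribosomal RNA genes at a two-sided Fisher's exact p of 0.0494, which met the condition written beforehand but rested on 1 of 82 genes (Sp100, at 70.3 CPM with hairpin 1 and 5.12 CPM with hairpin 2) against 8 of 14522. The annotation does not hold the full ribosomal RNA repeat, and IDs without a match, such as the 2 abundant ones, could not be searched. The test could therefore miss leftover ribosomal RNA. A minimum of 3 genes was then required after its result was seen, so leftover ribosomal RNA stays open as a possible explanation, and no biological explanation was tested.

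Erythroid, cell cycle, histone and ribosomal protein lists lay lower with both Bloodlinc hairpins, by calls of which 0 held with an estimated correlation or with fry. A gene length bias stays open by the number set beforehand, since 11 of the 14 lists called lower with the preset correlation alone stayed below the range of 95% of random lists matched on expression and exon length, 1 short of it, although the 3 others (hnRNP, splicing factor and mast cell genes) lay outside this pattern and all 9 lists within it stayed below, where matched lists had medians from −0.48 to −0.20. A control library that stands apart stays open, since both hairpins lay below all 3 controls in 5 of 14 lists and the control lay above the other 7 libraries in 6 of 14. Slower erythroid maturation with less Bloodlinc, the biological explanation, may account for the pattern. In the overexpression library 10 of 14 lists had a higher median, between the bounds set for and against it. That count took any median above 0, such as that of DNA replication genes (0.03), at percentile 50.5 of random lists. Of the 14 lists, 5 lay above the range of 95% of random lists. The knockdown of Bloodlinc RNA itself did not pass its test.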

How the results depend on the processing

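The settings with protein-coding genes only, without the hnRNPU hairpins, without the 2 unmatched IDs and mitochondrial ribosomal RNA, and with thinned libraries were chosen only after the data were seen. No paired analysis was possible because the hairpin numbers name different sequences and the controls carry none. Of the results on named genes in settings other than leaving out a hairpin, 1502 kept their direction and side of the threshold, 356 lost their call, 29 gained 1, 20 values without a test moved beyond their interval and 23 reversed. On leaving out a hairpin, 343 kept both, 125 lost their call, 1 gained it and 4 reversed. Shared calls were 0 in the settings run for them, which shows no stability, since 4 of the 6 had 0 Bloodlinc calls to share. Where no reason follows from the setting's construction, the cause was not tested.

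For the Bloodlinc knockdown (19 genes), 5 genes passed with DESeq2, 5 with robust estimation and 8 against 1.5-fold. With limma-voom, the filter of 5 CPM, the 3 libraries alone, the pooled controls, the hnRNPU hairpins left out and thinned libraries 0 passed, with 636, 278, 369, 1565, 504 and 280 at an unadjusted p under 0.05 by edgeR or limma-voom. Against the other control hairpin library 1043 passed, of which 24.7% rose against 78.9% of the 19. Leaving out each hairpin library gave 0 to 63.

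For the hnRNPU knockdown (135), 9 passed with limma-voom, 8 with 5 CPM, 65 with robust estimation, 7 with pooled controls, 70 against 1.5-fold, 8 when thinned and 2340 with the other control. Leaving out each hairpin gave 7 to 121. Of the 135, 65.9% rose, and the share that rose was 76.8% with DESeq2's size factors, 79.8% with upper quartile scaling, 46.2% with robust estimation, 60.5% with the 20 most abundant genes removed, 55.9% with the other control and 86.5% in the 3 libraries alone. For the difference of the effects (50), 22 passed with DESeq2, 3 with limma-voom, 5 with 5 CPM, 23 with robust estimation and 1 when thinned, and 6 to 37 when a hairpin was left out. The stricter filter tests fewer genes and thinning leaves fewer counts.

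With an estimated correlation 0 lists passed in either knockdown, and 0 with fry. Leaving out a hairpin gave 11 to 16 and 14 to 20 lists. The correlation between knockdowns was 0.220 at 5 CPM and 0.0312 to 0.174 without a hairpin. All 5 genes called by DESeq2 in the Bloodlinc knockdown (100%) had the opposite sign in the overexpression pair, and at 5 CPM no call gave a value. The 100% rests on few genes, beside 63.2% of the 19 calls and 50.8% of other genes. Of the 19, 0 were 2-fold apart in the opposite direction. Genes at least 2-fold apart in that pair were 615 at a prior count of 0.5, 7 at 10, 4 at 5 CPM and 2526 against the median of the 3 controls.

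In the Bloodlinc knockdown the log2 fold change turned to 0.0216 for Hnrnpu without Bloodlinc hairpin 2 (−0.42 to 0.0216 over the hairpins left out), and against the other control hairpin to 0.0774 for Slc4a1, 0.16 for Fos, 1.35 for Alas2, 0.0671 for Nusap1, −0.0230 for Csf1r and −0.16 for Steap3. Alas2 was at 0.37 against the pooled controls. In the hnRNPU knockdown it turned to 0.27 for Hnrnpu with the other control, −0.00674 for Usp18 without hairpin 1 (up to 7.21 without another) and −0.60 for Hbb-y without hairpin 2 (up to 3.63). Slc4a1 turned to 0.10 with DESeq2 and with its size factors, 0.13 with upper quartile scaling, 0.15 with 5 CPM and without hairpin 2 (down to −0.32 without hairpin 1), 0.11 in the 3 libraries and 0.14 when thinned. Against the median of the 3 controls, which differ widely, the overexpression library was at −1.85 for Slc4a1, −0.57 for Hbb-bt, −1.41 for Alas2, −0.88 for Tmod1, −1.22 for Klf3, 0.82 for Myb, −1.17 for Mki67, 0.64 for mt-Nd2 and 5.45 for Mrc1. At the depth of the hnRNPU hairpins, a 2-fold change was recovered in 0% of simulated genes.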

Other observations

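The placing of lists among random lists was planned, and the other values of this part were chosen only after the result was seen. In the overexpression pair, other lists outside the range of random lists were small in size. Interferon-induced genes had a median log2 difference of −0.14, heat shock and immediate early genes −0.09, glycolysis genes −0.04 and ribosomal protein genes −0.02. Cholesterol synthesis genes, had a median of 0.09. Genes of the unfolded protein and amino acid response had 0.08, with Trib3 at 0.45 (0.37 to 0.53), and EPO-STAT5 target genes 0.09. Of 12 genes beside Slc4a1 on chromosome 11, 9 were higher (median 0.13). The proliferation gene Mki67 stood at 0.19 (0.18 to 0.21), with no list call for mitosis genes (median 0.07).

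Outside the naming rule and chosen after their values were seen, the metallothionein gene Mt1 and the red cell membrane gene Smim1 fell in the hnRNPU knockdown (log2 fold changes −2.17, SE 0.60, and −2.28, SE 0.54). Vim, an intermediate filament gene of mesenchymal cells, stood at 1.67 (adjusted p = 0.208) and Grn, a gene beside Slc4a1, at 1.95 (adjusted p = 0.133). Small nucleolar RNAs took 1.46%, 1.29% and 0.918% of the counts in genes in the Bloodlinc control, hairpin 1 and hairpin 2 libraries, against 0.0947% to 0.181% in the other 5. Between libraries, the chi-square per degree of freedom over genes was lowest, at 11.6, for the empty and Bloodlinc vectors, and 30.1 for the hnRNPU hairpins.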
